A study of Homo sapiens with 47 samples.

How the data were processed

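The labels describe uSpyCLIP-seq of Lenti-X 293T cells that stably expressed the protein of interest, were irradiated on ice with ultraviolet light and had their RNA fragmented with RNase I. The submitters' processing notes name Trim Galore 0.0.6, STAR 2.7.9a and the build hg38. The cluster or peak caller, its thresholds, any removal of duplicates and whether the libraries of a group were pooled are not given in the sources used here. The deposited lists, 1 per group, are each tied to the first library of the group. They hold positions and no measured values, and the deposited columns are chromosome, start, end and strand, with dots in place of name and score. Starts were counted from 0 in the files and are given here from 1. The sites of PTBP1, RBFOX2 and the SpyCatcher comparison are called clusters here and are narrow, and those of Cas13 are wider (median 124 to 177 nt). All lists are restricted to chromosomes 1 to 22, X and Y. The Cas13 lists are not sorted by position, and the basis of their order is not stated.

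The unit of analysis was the site. Sites overlapped when they shared at least 1 nt on the same strand. Each observed share was set beside the mean share of 100 random placements (20 for the 100000-cell list) of the same widths and strands within the same gene, where sites outside genes moved by up to 10000 nt. A second control, chosen after seeing the data, moved each site by 200 to 1000 nt. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. There is 1 list per group and no count of reads, so no test between groups was made and no p-value is given, and the depth of each library is unknown.

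Genes came from RefSeq gene spans of GRCh38.p14, the same assembly as hg38, which were used without strand or exons. The strand of a gene was inferred from PTBP1 clusters of the 10000000-cell list: a gene with at least 3 clusters outside other genes, or else in its whole span, and at least 90% of them on 1 strand, took that strand. Of 59679 genes, 13728 received a strand. Of 8808 genes with at least 10 such clusters, 98.9% had at least 90% on 1 strand. A gene whose antisense neighbour is the more strongly bound can receive the wrong strand. A site went to the gene over its midpoint on the same or an unknown strand, with small RNA genes before protein-coding, long noncoding and pseudogenes, and the shortest gene on ties. Positions relative to the 3′ end used protein-coding genes of inferred strand, with 100 random placements, or 10 for the 4 longest lists. XIST and genes on chromosome Y were left out of gene-level results.

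Choices made before the data were examined were the comparisons, the overlap rule, the alternatives to it, the gene lists and the rule for naming genes. That rule names a targeted gene and its paralogs, up to 8 members of each gene list that a comparison is about and the 10 genes with most sites in a list. Parts of it that need scores or sequence could not be applied. The gene lists held genes with splicing events linked to PTBP1 or RBFOX2, RNAs that scaffold ribonucleoproteins, long noncoding RNAs, mitochondrially encoded RNAs, ribosomal proteins, replication-dependent histones, abundant transcripts, self-regulating splicing factors and Polycomb repressive complex 2. The number of clusters or sites in a list of protein-coding genes was set against 10000 random gene sets matched on the number of PTBP1 clusters at 10000000 cells in 20 bins, and the percentile describes these lists only. Mitochondrial genes lie outside the chromosomes in the lists and have no result.

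The planned analyses of motifs, base composition, sequence shared with the targeted site and classes of exons and introns need a genome sequence or exon annotation, which were not used here. Those that need a score were not run either. Classes of genes and distance from the 3′ end took their place. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and bedtools 2.31.1. The overlap, strand and gene assignment code was tested on simulated data. In 4 settings of overlap, 2000 simulated sites gave 0 answers that differed from a search of all pairs. In 400 simulated genes every strand was recovered (100.0%), and 39.8% overlap was found where 40% had been planted. The simulated genes did not overlap and held sites on their own strand only, so overlapping and antisense genes were not tested.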

Results

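Protein contacts with RNA were mapped in Lenti-X 293T cells, a human embryonic kidney line used to package lentivirus, by uSpyCLIP-seq. In this assay ultraviolet light crosslinks a tagged protein to RNA, the complex is captured through the covalent bond between SpyTag and SpyCatcher, and the RNA fragments still bound are sequenced. The 47 libraries fall into 20 groups. The splicing regulator PTBP1 was profiled from 10000000, 100000, 10000 and 1000 cells with 2 libraries each, and RBFOX2, another splicing regulator, from 10000000 cells with 2 libraries. SpyCatcher versions 1.0 and 2.0 were compared at 20 and 40 µg with 1 library each. The catalytically dead RNA-targeting nucleases dPspCas13b and dRfxCas13d were profiled without guide RNA and with guides such as EZH2g1 and EZH2g2, with 3 libraries each. Site lists of 15 groups are described here, 1 list per group. Lists of the uncrosslinked libraries of either Cas13 protein and of dRfxCas13d with gNT were not analysed here.

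The lists give positions and strands on hg38 and no score, read count or library total, so the sequencing depth behind a site is unknown. With 1 list per group there is no spread between replicates and no p-value. Intervals in parentheses are exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Gene positions below are from RefSeq gene spans, which do not part exons from introns or untranslated regions here.

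The PTBP1 lists address how far the assay reaches as the number of cells falls. PTBP1 clusters covered 14616 genes at 10000000 cells, 13344 at 100000, 10474 at 10000 and 6883 at 1000. PTBP2, the neuronal paralog of PTBP1, held 411, 394, 202 and 66 clusters at these inputs. PKM, the pyruvate kinase gene with a pair of mutually exclusive exons, held 177, 158, 128 and 38. The kinesin gene KIF1B went from 385 clusters at 10000000 cells to 255, 84 and 5, and the reticulon gene RTN4 from 254 to 206, 71 and 5.

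Of 25 genes listed for splicing events linked to PTBP1, 22 held a cluster at 10000000 cells, 21 at 100000, 19 at 10000 and 14 at 1000. PTBP3, a further paralog, held 210, 206, 75 and 3 clusters. The tropomyosin gene TPM3 held 177, 147, 64 and 10. The actinin gene ACTN1 held 179, 109 and 27 and then 0, and the oligosaccharyltransferase gene RPN2 held 101, 68 and 11 and then 0. In the 1000-cell list these 25 genes held 152 clusters, against a mean of 86.5 in 10000 random gene sets with matching numbers of clusters at 10000000 cells (percentile 95.7). PTBP2 and PKM held most of these 152, and the number of members with a cluster, 14, lay below the random mean of 15.4 (percentile 24.1). At 100000 cells they held 2163 clusters against a random mean of 2293 (percentile 37.8). The random sets here and below were not matched on strand. At 1000 cells minus-strand protein-coding genes held 3.92% of their number of clusters at 10000000 cells, and plus-strand genes 2.05%.

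Genes of splicing factors that regulate their own transcripts held more clusters than matched genes, and not at low input alone. They held 1583 clusters at 100000 cells against a random mean of 1324 (percentile 97.7). In the RBFOX2 list from 10000000 cells they held 583 against 212. All 21 listed members, such as TIA1, TIAL1 and SRSF11, held a cluster at 10000 cells, with 1191 clusters in total against a random mean of 449. At 1000 cells 19 members held 185 clusters against 56.05. TIAL1 held 133, 152, 123 and 30 clusters from the highest to the lowest input, and SRSF11 held 209, 173, 133 and 36. The 24 listed abundant transcripts of cultured cells held 151 clusters at 1000 cells against a random mean of 37.5, among them HNRNPA2B1 with 35 and YWHAZ with 29. Ribosomal protein genes held clusters in 78, 73, 68 and 30 of 86 members.

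The genes with most clusters changed along the titration. At 10000000 cells these were the long genes TTC28 with 1651 clusters, FHIT with 1507, DIAPH3 with 1489, LRBA with 1484 and ROBO1, an axon guidance receptor, with 1459. At 1000 cells they were HELLS, a chromatin remodeller, with 146, SLIT2, a ROBO1 ligand, with 140, ANKRD17 with 118, the SR protein kinase gene SRPK1 with 108 and RBM26 and the noncoding RNA FTX with 106 each. TTC28 held 31 clusters there and ROBO1 held 46. HELLS had held 526 at 10000000 cells and SLIT2 710.

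The lists held 964422, 769524, 248168 and 30911 clusters from the highest to the lowest input, with a median width of 6 nt and of 5 nt at 1000 cells. They covered 8082, 5750, 1631 and 165 kb. The 100000-cell list was 79.8% as long as the 10000000-cell list, the 10000-cell list 25.7% and the 1000-cell list 3.21%. Of the clusters at 100000 cells, 55.8% (55.7 to 55.9) overlapped a cluster at 10000000 cells by at least 1 nt on the same strand. The share was 75.3% (75.1 to 75.4) at 10000 cells and 71.5% (71.0 to 72.0) at 1000 cells. Random places in the same genes gave 3.18%, 4.27% and 4.88%, and clusters moved by 200 to 1000 nt gave 8.47%, 13.1% and 14.4%. Against a reference drawn to 30911 clusters the shares were 1.91%, 2.46% and 2.28%.

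**Figure D1:**
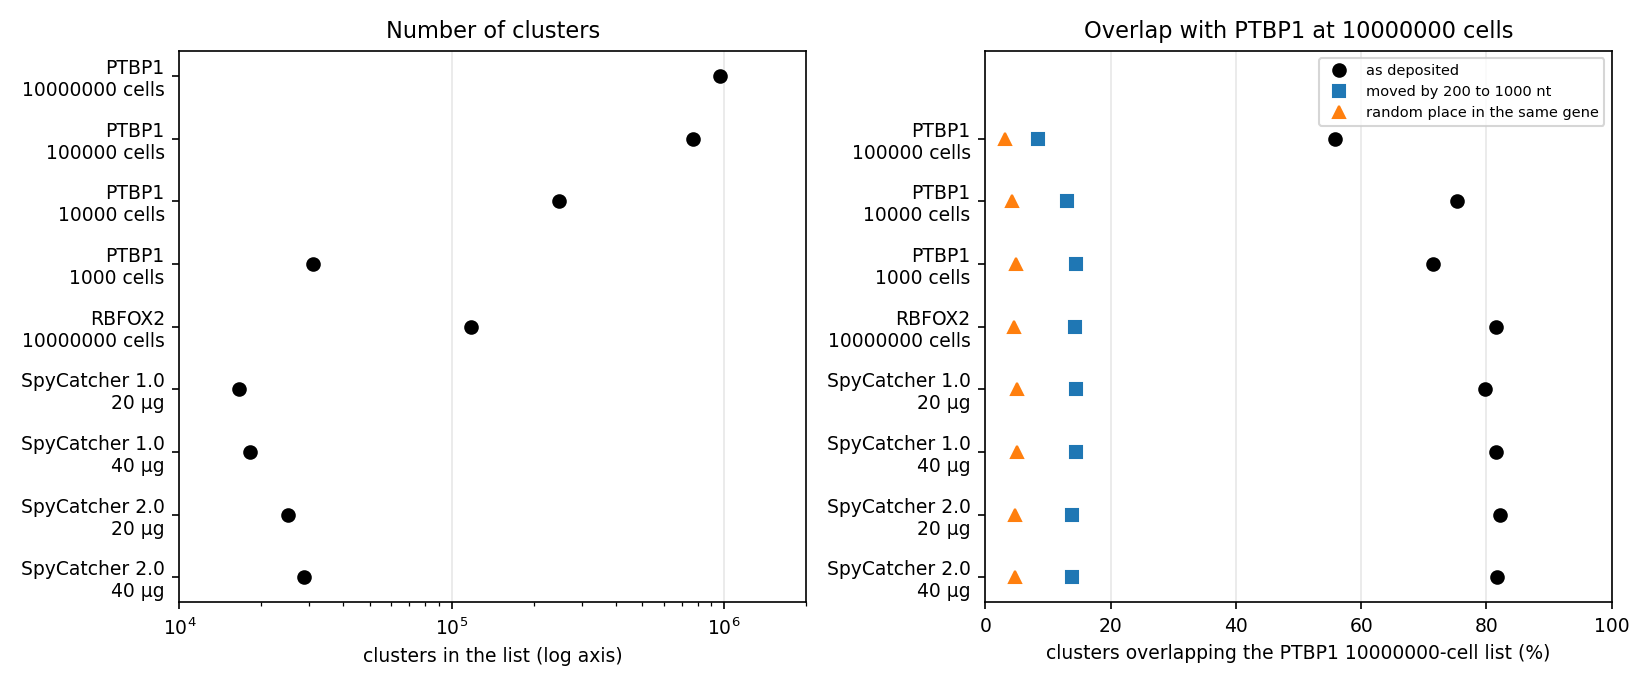
Left, number of clusters in each of 9 lists on a log axis; right, the percent of clusters of 8 lists that overlapped the PTBP1 list from 10000000 cells, as deposited (circles), after a move of 200 to 1000 nt (squares) and at random places in the same gene (triangles). Observed shares lay between 55.8% and 82.1% and the moved clusters between 8.47% and 14.5%.

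Protein-coding genes held 94.1% of PTBP1 clusters at 10000000 cells, 94.1% at 100000, 93.9% at 10000 and 91.3% at 1000. Long noncoding genes held 3.21%, 3.28%, 3.35% and 4.53%, and small RNA genes 0.08%, 0.07%, 0.15% and 0.39%. The last 2000 nt of protein-coding genes held 7.67%, 4.48%, 9.32% and 12.02% of the clusters in those genes, against 3.97%, 3.53%, 4.93% and 6.11% at random places in the same genes. The share of clusters on the minus strand was 54.0% (53.9 to 54.1), 55.4% (55.3 to 55.6), 61.2% (61.1 to 61.4) and 69.3% (68.8 to 69.8) from the highest to the lowest input. It was 60.2% (59.9 to 60.4) for RBFOX2 and between 59.8% and 62.3% for the SpyCatcher lists, and it lay between 50.8% and 54.2% in the 6 Cas13 lists.

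**Figure D2:**
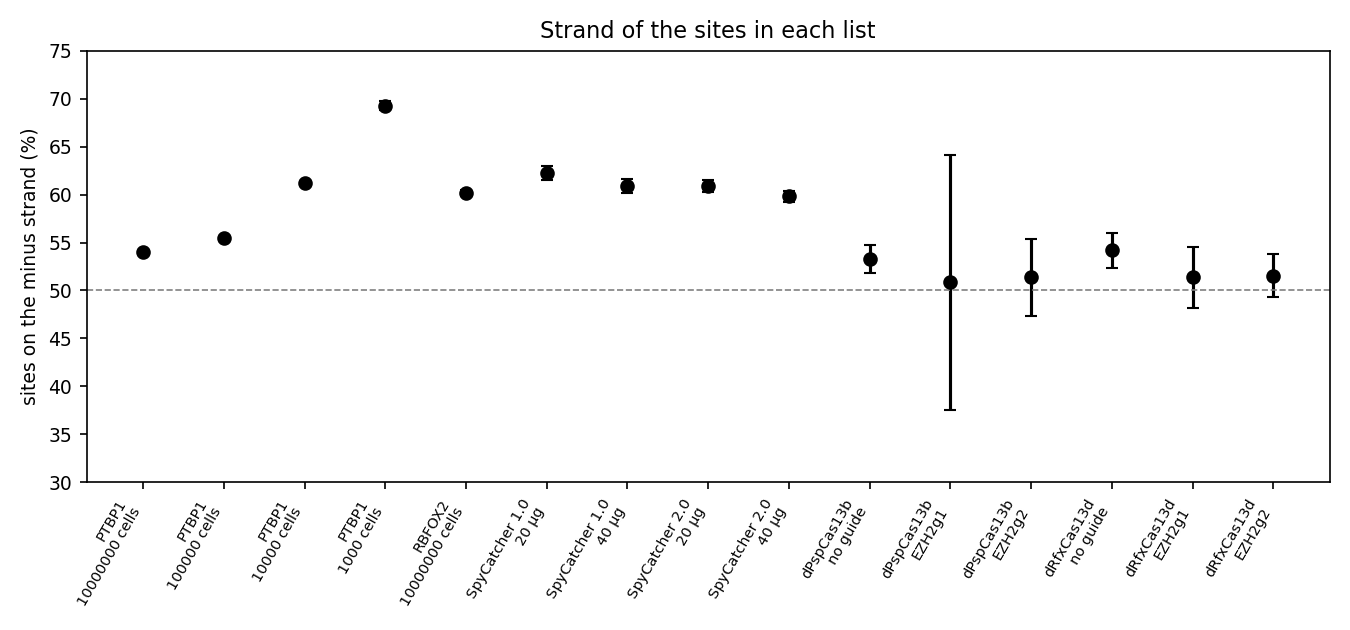
Percent of sites on the minus strand in each of 15 lists, with exact binomial 95% intervals as bars and a dashed line at 50%. The PTBP1 lists went from 54.0% at 10000000 cells to 69.3% at 1000 cells, and the Cas13 lists stayed between 50.8% and 54.2%.

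RBFOX2 was profiled as another protein by the same assay. Its 117590 clusters lay in 8635 genes. Among genes with splicing events linked to RBFOX2, the actin regulator ENAH held 297 clusters, the translation factor gene EIF4G3 265, the catenin gene CTNND1 91, MAP3K7 85, MBNL1 74, DNM2 67, EPB41 67 and NUMB 62. The genes with most clusters were SLIT2 with 469, ANKRD17 with 368, the noncoding RNA JPX with 355 and HELLS with 344.

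Of the 24 genes in the RBFOX2 group, 20 held a cluster against a random mean of 19.1 (percentile 77.3), with 1252 clusters in total against a mean of 644 in matched random gene sets (percentile 99.8). ENAH held 297 and EIF4G3 held 265 of the 1252. The same genes held 2298 clusters in the PTBP1 list from 10000 cells against 1334 (percentile 99.8) and 322 at 1000 cells against 143. EIF4G3 held 684 and ENAH 307 of the clusters at 10000 cells, and 80 and 95 of those at 1000 cells. At 10000 cells 20 members had a cluster against 20.1 (percentile 46.6). The 25 genes linked to PTBP1 held 547 clusters in the RBFOX2 list against 354 (percentile 96.3). PTBP2 held 135 and PKM 73 of the 547, and the 19 members with a cluster compare with a random mean of 19.1 (percentile 44.9). Whether the other members of either group held an excess without these leading genes was not computed.

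RBFOX2 clusters overlapped PTBP1 clusters from 10000000 cells in 81.6% of cases (81.3 to 81.8), a larger share than the PTBP1 clusters from any lower input. They overlapped the 100000-cell list in 79.4%, the 10000-cell list in 51.8% and the 1000-cell list in 10.5%. Random places in the same genes gave 4.61% for the 10000000-cell list and local moves 14.2%. Protein-coding genes held 94.2% of RBFOX2 clusters, and the last 2000 nt of those genes held 7.68%. Motifs of either protein were not analysed here, since no genome sequence was used.

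The next libraries compared SpyCatcher versions 1.0 and 2.0 for the efficiency of capture. Their sample labels name no captured protein, while the names of the deposited lists say PTBP1. At 20 µg the version 1.0 list held 16507 clusters in 4921 genes and the version 2.0 list 25028 in 5866 genes. At 40 µg the numbers were 18228 clusters in 5102 genes and 28586 in 6138 genes. ROBO1 led every one of these 4 lists, with 110 and 108 clusters for version 1.0 and 138 and 171 for version 2.0 at 20 and 40 µg. SLIT2 held 72, 87, 130 and 131 in the same order, and ANKRD17 held 58, 82, 95 and 104.

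Version 2.0 gave 1.52 times as many clusters at 20 µg and 1.57 times as many at 40 µg, and 1.19 times as many genes at 20 µg. From 20 to 40 µg the number of clusters changed less than between versions at either amount. Of the 25 genes linked to PTBP1, 18 and 14 held a cluster with version 1.0 at 20 and 40 µg and 19 at both amounts with version 2.0. Their clusters numbered 96, 89, 123 and 136, against random means of 45.4, 51.0, 71.7 and 81.3 (percentiles 98.8, 96.9, 97.1 and 96.5). In number of clusters the excess was not particular to these genes. The 24 genes linked to RBFOX2 held 171, 165, 237 and 280 clusters against 75.5, 86.0, 121 and 141 (percentiles 99.1, 97.9, 98.6 and 98.7). By members with a cluster, the PTBP1-linked genes lay at percentiles 99.7, 72.1, 98.7 and 98.1. The RBFOX2-linked genes lay at 96.1, 94.0, 79.6 and 90.6. Among the PTBP1-linked genes PTBP2 held 26, 25, 30 and 42 clusters, PKM 21, 23, 22 and 25, and TPM3 9, 10, 12 and 10.

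Clusters of the 4 lists overlapped PTBP1 clusters from 10000000 cells in 79.7% (79.1 to 80.3) and 81.6% (81.0 to 82.1) for version 1.0 and in 82.1% (81.6 to 82.6) and 81.7% (81.3 to 82.2) for version 2.0. They overlapped RBFOX2 clusters in 52.8%, 53.7%, 50.5% and 49.0%. Version 1.0 clusters overlapped those of version 2.0 in 35.1% at 20 µg and 37.0% at 40 µg, and the version 1.0 list from 20 µg overlapped that from 40 µg in 29.5%. Each of these groups is 1 library, so the difference between versions has no replicate check, and equal sequencing depth of the libraries is not known.

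The Cas13 libraries without guide address binding that does not need a guide RNA. Both proteins had sites in many genes listed for abundant transcripts, though background capture cannot be told apart without the uncrosslinked lists. dPspCas13b sites lay in 2063 genes, led by the chromatin protein gene NUCKS1 with 33 sites, the phosphatase gene PTP4A2 and the mitochondrial import receptor gene TOMM20 with 18 each, TMBIM6 with 17 and GLO1 and SLC38A2 with 16 each. dRfxCas13d sites lay in 1946 genes, led by the clathrin heavy chain gene CLTC with 13, the tRNA synthetase gene IARS1 with 10, ATP5F1B and HSP90AA1 with 9 each and DYNC1H1, KHDRBS1 and PRKDC with 8 each. The proteins shared 734 of these genes.

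Ribosomal protein genes held 95 sites in 41 of 86 members with dPspCas13b, against a mean of 18.5 sites in random gene sets matched on the number of PTBP1 clusters. They held 64 sites in 37 members with dRfxCas13d against 12.75. RPS20 had 5 sites with dPspCas13b and 4 with dRfxCas13d, RPS15A had 5 and 3, and RPL11 had 2 and 4. The 24 abundant transcripts held 71 sites in 18 members with dPspCas13b against 8.99, and 41 sites in 17 members with dRfxCas13d against 5.17. The chaperone gene HSPA8 had 12 and 5 sites, HSP90AB1 7 and 3, HSP90AA1 4 and 9, and YWHAZ 10 and 1. Replication-dependent histone genes held 18 sites in 11 of 69 members with dPspCas13b against 3.65, with 4 in H4C2 and 3 in H3C2, and 13 sites in 10 members with dRfxCas13d against 3.33. These observed numbers lay at percentile 99.7 or above of the random sets, which do not match the level of mature messenger RNA. Genes of self-regulating splicing factors held 30 sites in 13 of 21 members with dPspCas13b (percentile 98.7) and 10 in 6 members with dRfxCas13d (percentile 90.9).

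The dPspCas13b list held 4701 sites with a median width of 124 nt, or 3436 after sites that overlap were merged. The dRfxCas13d list held 2808 with a median width of 172 nt, or 2663 after merging. Protein-coding genes held 98.2% of the sites of either protein. Within those genes, 45.7% (44.2 to 47.1) of dPspCas13b sites and 30.2% (28.4 to 32.0) of dRfxCas13d sites lay in the last 2000 nt, against 10.9% and 11.2% at random places in the same genes. Of the dPspCas13b sites, 11.7% (10.8 to 12.7) overlapped a dRfxCas13d site, and 14.1% (12.8 to 15.4) did so in the other direction. Random places gave 1.85% and 2.17%, and local moves 3.66% and 4.37%. PTBP1 clusters from 10000000 cells were overlapped by 50.6% of dPspCas13b sites and 36.6% of dRfxCas13d sites, with 29.5% and 23.1% after local moves.

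Guides against EZH2, the methyltransferase subunit of Polycomb repressive complex 2, address binding that depends on the guide. EZH2 spans 148807383 to 148884291 of chromosome 7 on the minus strand. With EZH2g1, dPspCas13b had a site at 148819567 to 148819738, which stood first in its list, and dRfxCas13d had a site around it at 148819524 to 148819755, at place 74 of 966. Neither protein had a site there with EZH2g2 or no guide. A stretch nearer the 3′ end of the gene was listed for both proteins with both EZH2 guides. It ran from 148818032 to 148818173 with dPspCas13b and EZH2g1, from 148818039 to 148818168 with dPspCas13b and EZH2g2, and from 148817924 to 148818247 with dRfxCas13d and EZH2g2. With EZH2g1, dRfxCas13d had 2 overlapping sites there, from 148817890 to 148818057 and from 148817972 to 148818186.

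dRfxCas13d also had a site in EZH2 at 148815733 to 148815906 with EZH2g2. Neither no-guide list held a site in EZH2. The paralog EZH1 held none in the 6 Cas13 lists. Among the 7 listed genes of Polycomb repressive complex 2, dRfxCas13d with EZH2g2 had 6 sites in 4 genes, namely 2 in EZH2 itself, 2 in EED and 1 each in JARID2 and RBBP7. Without guide it had 4 sites in 2 of these genes, 3 in RBBP7 and 1 in RBBP4, and dPspCas13b had 5 in 3 genes. The order of lines in the lists has no stated meaning, and the guide sequences are not given in the sources used here.

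**Figure D3:**
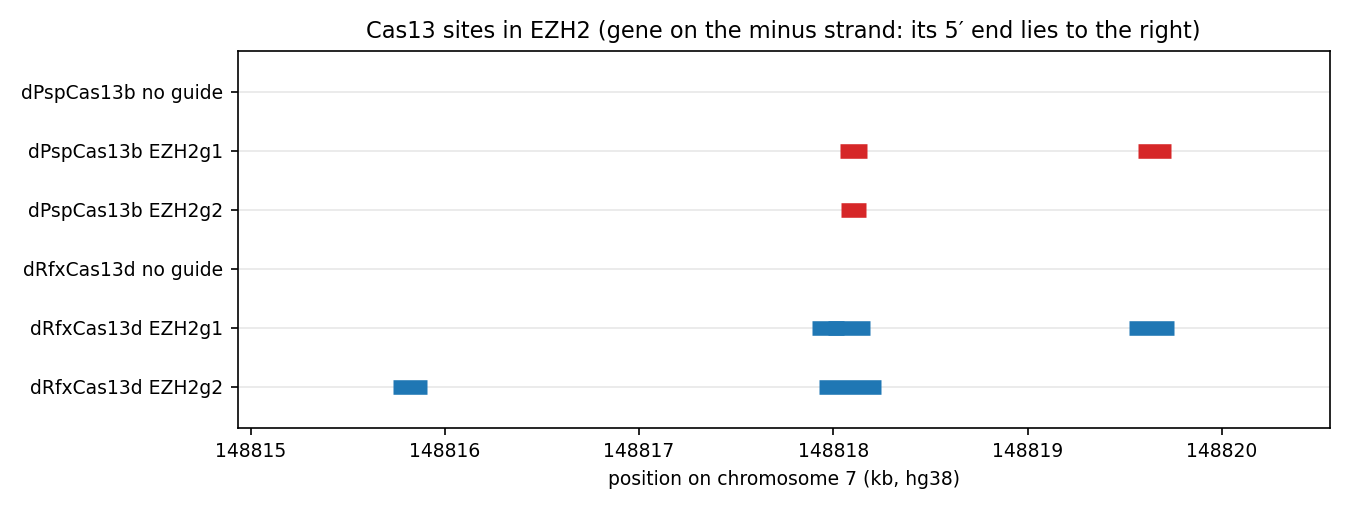
Cas13 sites in EZH2, by position on chromosome 7 in kb of hg38, with 1 line for each of 6 Cas13 lists, dPspCas13b in red and dRfxCas13d in blue. Both proteins had a site near 148819567 with EZH2g1 alone, and both had a site near 148818039 with EZH2g1 and also with EZH2g2.

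Over whole lists, EZH2 included, sites of the guide lists were shared between the proteins by guide. Of the 59 sites of dPspCas13b with EZH2g1, 40 overlapped a site of dRfxCas13d with the same guide, or 67.8% (54.4 to 79.4). With EZH2g2 the share was 52 of 625, or 8.32% (6.28 to 10.8). Random places in the same genes gave 3.44% and 0.522%. With the other EZH2 guide or none, the share of these dPspCas13b sites overlapping a dRfxCas13d list ranged from 0.80% to 3.39%. In the other direction, 4.45% of dRfxCas13d sites with EZH2g1 and 2.11% with EZH2g2 overlapped the dPspCas13b list of the same guide. Guide lists overlapped the no-guide list of their own protein in 1.69% and 2.72% of dPspCas13b sites and 2.28% and 1.25% of dRfxCas13d sites with EZH2g1 and EZH2g2.

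Among the EZH2g1 sites common to both proteins, the 4 outside EZH2 with the longest shared stretch, named after their values were seen, lay in ITM2B, in the histone demethylase gene KDM6A, in SEC63 and in SH3GLB1. The ITM2B site ran from 48261494 to 48261671 of chromosome 13 in the dPspCas13b list and the KDM6A site from 45070063 to 45070222 of chromosome X. With EZH2g2 the longest were in RPL14, at 40461937 to 40462203 of chromosome 3, and in PLEKHB2, at 131147249 to 131147448 of chromosome 2.

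**Figure D4:**
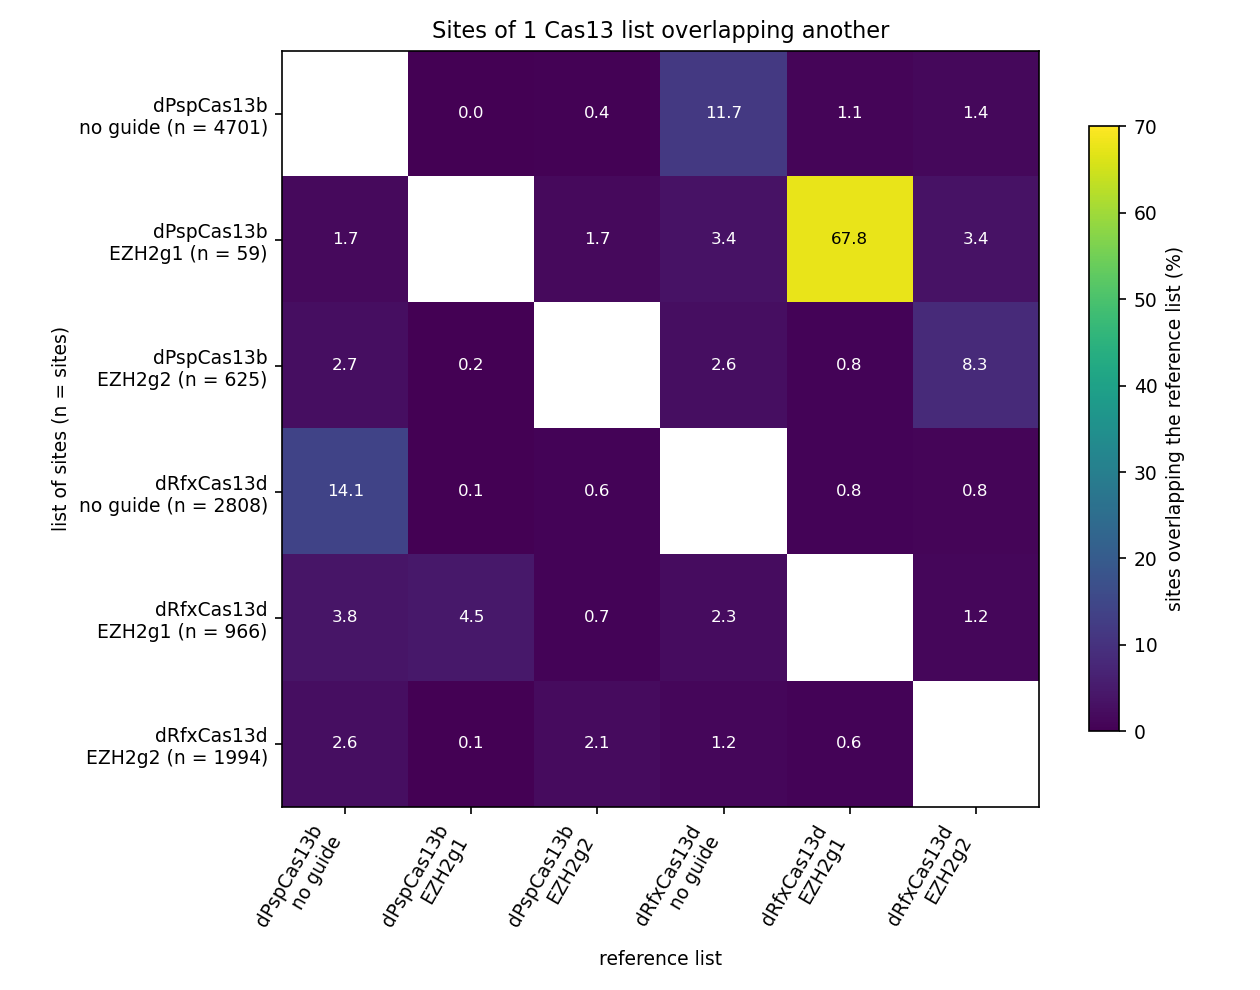
Percent of the sites of each Cas13 list (rows, with the number of sites) that overlapped each other list (columns), by colour and printed value. The highest cells pair the same guide in both proteins from the dPspCas13b side, at 67.8% for EZH2g1, and the lists without guide, at 11.7% and 14.1%.

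The number of sites differed by guide and protein. dPspCas13b had 59 sites in 55 genes with EZH2g1 and 625 in 516 genes with EZH2g2, and dRfxCas13d had 966 in 835 and 1994 in 1100 genes. The genes with most sites were ATF6, EZH2, MBIP and MNX1 with 2 each for dPspCas13b with EZH2g1, and ARL2, PTTG1IP, SLC3A2 and TRPC4AP with 5 each for dPspCas13b with EZH2g2. For dRfxCas13d they were DYNLT1, MEA1 and SF3B5 with 4 each with EZH2g1. dRfxCas13d with EZH2g2 had 58 sites in PLEC, which encodes the cytolinker plectin, 32 in the myosin gene MYH9, 24 in CEP250, 20 each in CEP131 and MYH14, 19 each in FYCO1, NUMA1 and PCNT, 18 in RRBP1 and 16 in GOLGA2.

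The last 2000 nt of protein-coding genes held 25.9% and 27.8% of dPspCas13b sites in such genes with EZH2g1 and EZH2g2, and 24.3% and 15.8% of dRfxCas13d sites, all below the shares of the same protein without guide. With 59 to 1994 sites per list, the intervals of the smaller lists are wide, and sites that overlap others in 1 list are not independent of each other.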

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

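Values were recomputed with sites that share at least 50% of the shorter site, that lie within 50 nt or that lie on either strand, with sites within 20 nt merged, with genes taken by any overlap or from protein-coding genes alone, and with a reference drawn to 30911 clusters. The limit of 1000 nt from the 3′ end and the drawn reference for RBFOX2 were chosen after seeing the data. Alternatives by score, and motif, base composition and shared-sequence alternatives were not run. No paired analysis was possible because each condition has 1 list and the lists carry no values per library. No library could be left out for the same reason. Counting either strand kept all 16 overlap shares within their intervals, and any overlap kept the share in protein-coding genes within its interval in all 15 lists.

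With at least 50% of the shorter site shared, overlap with PTBP1 at 10000000 cells was 52.4%, 72.5% and 69.4% for 100000, 10000 and 1000 cells, 79.2% for RBFOX2, 77.4% and 79.3% for SpyCatcher 1.0 at 20 and 40 µg, and 79.55% and 79.2% for version 2.0. Within 50 nt these became 79.7%, 88.5%, 80.4%, 91.5%, 89.5%, 91.2%, 92.1% and 92.2%. The 100000-cell share was then close to that at 1000 cells. Against the drawn reference the shares were 1.91%, 2.46%, 2.28% and 2.65% for 100000, 10000 and 1000 cells and RBFOX2; a shorter reference gives this by construction. RBFOX2 stayed above the lower PTBP1 inputs under the 50% rule and within 50 nt. The drawn reference kept this order too, but it thins the same list at random and is no separate check.

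Without guide, the 50% rule gave 9.53% of dPspCas13b and 12.4% of dRfxCas13d sites shared, and within 50 nt 13.3% of dPspCas13b sites. For guide against no guide the 50% rule gave 0.00% and 1.28% for dPspCas13b with EZH2g1 and EZH2g2, and 0.80% for dRfxCas13d with EZH2g2. The shares of sites common to both proteins with 1 guide stayed within their intervals under every overlap setting. Merging left 535340 PTBP1 clusters at 10000000 cells and 470842 at 100000, and moved no other list by over 1.5 times. With protein-coding genes alone, their share was 94.2% for PTBP1 at 10000000 cells and 98.7% for dRfxCas13d without guide. Within 1000 nt of the 3′ end lay 29.8% of dPspCas13b and 18.2% of dRfxCas13d sites without guide. By any overlap, 1 gene of Polycomb repressive complex 2 in place of 2 held a dRfxCas13d site without guide. The cause was not tested where construction does not give it.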

Other observations

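RNAs that scaffold ribonucleoproteins held clusters in the PTBP1, RBFOX2 and SpyCatcher lists, and no sites of either Cas13 protein without guide or with an EZH2 guide. Of 28 such RNAs, 15, 14, 13 and 13 held a PTBP1 cluster from the highest to the lowest input, and 13 held an RBFOX2 cluster. RPPH1, the RNA of ribonuclease P, held 11 clusters at each of 10000000, 100000 and 10000 cells and 7 at 1000 cells, and 11 in the RBFOX2 list. RMRP, the RNA of the related ribonuclease MRP, held 6, 3, 6 and 5, and the spliceosomal RNA gene RNU12 held 4, 2, 5 and 3. The group took 0.006% of the clusters at 10000000 cells and 0.12% at 1000 cells. The 6 Cas13 lists hold only 59 to 4701 sites, each at least 107 nt wide. Their lack of sites in these short RNAs therefore does not show that the RNAs are avoided.

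Long noncoding RNAs differed among themselves. FTX held 674, 826, 703 and 106 PTBP1 clusters as the input fell, PVT1 held 502, 602, 120 and 3, and MALAT1 held 41, 45, 50 and 26. NEAT1, the scaffold of paraspeckles, held 0, 0, 1 and 2 PTBP1 clusters, 14 RBFOX2 clusters and 9, 10, 10 and 16 in the SpyCatcher lists. Of 13 listed genes of this kind, 9 were assigned a cluster at 10000000 cells and 9 at 1000 cells. KCNQ1OT1 and SNHG14 were assigned none, though at least 3 clusters at 10000000 cells lay in the span of each. Those clusters went to overlapping genes, so a lack of binding is not shown for these RNAs. With dPspCas13b without guide, NORAD held 4 sites and GAS5 held 3.

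Of the tests below, those of chromosomes, moved clusters, equal-size RBFOX2 draws, the intervals of other dRfxCas13d lists and matched gene sets in those lists were chosen after the result was seen. The minus-strand share of PTBP1 clusters went from 54.0% at 10000000 cells to 69.3% at 1000. A few genes do not account for this, since the share at 1000 cells was 67.4% without the 100 genes with most clusters. Nor does a larger number of clusters in minus-strand genes to begin with: in 20 bins of genes with like numbers at 10000000 cells, the number of clusters at 1000 cells, divided by that at 10000000 cells, was higher for minus-strand genes in every bin, by a median factor of 2.11. The factor was above 1 on 23 of 23 chromosomes, from 1.27 to 4.12, which is consistent with a strand-dependent step of library making or cluster calling. No biological explanation was tested, and the step itself stays open.

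RBFOX2 clusters overlapped PTBP1 clusters from 10000000 cells in 81.6% of cases, above the 55.8%, 75.3% and 71.5% of PTBP1 clusters from 100000, 10000 and 1000 cells. More PTBP1 clusters at the distances of the local move do not account for the difference from 1000 cells. The share of moved clusters that overlapped was 0.99 times as large for RBFOX2, while the observed share was 1.14 times as large. The shortest move was 200 nt, so this control cannot test for more PTBP1 clusters closer by, which stay open. Counting clusters within 50 nt of a PTBP1 cluster, the shares were 91.5% for RBFOX2 and 80.4% for 1000 cells. More PTBP1 clusters at either distance stay open for the difference from 10000 and 100000 cells. There the moved share was 1.09 and 1.68 times as large for RBFOX2 and the observed share 1.08 and 1.46 times. Positions that crosslink whichever protein is captured may contribute: 11.6% of 1000-cell PTBP1 clusters overlapped an equal-size draw of the RBFOX2 list, 0.91 times the 12.8% on a line through the 3 longer PTBP1 lists, which had to be extended beyond their lengths. True binding of both proteins at the same places stays open, as no motif and no uncrosslinked list was examined.

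dRfxCas13d with EZH2g2 had 245 of 1994 sites in its 10 leading genes, among them PLEC, MYH9 and CEP250, many of which encode coiled-coil proteins; the same genes held 2 sites without guide. A hypothesis is that EZH2g2 pairs with a sequence that such genes share. In 161 other genes named CCDC, CEP, KIF, GOLGA or MYH, the share of sites was 2.41% (1.78 to 3.18) with EZH2g2. It was 0.50% without guide, a ratio of 4.82. Of these 161 genes, 21 held a site with EZH2g2, 48 sites in all, and 12 held a site without guide. KIF7 held 10 of the 48 sites and CCDC88C 7, so a shift across the whole family is not shown. The lower bound of 1.78% lay above the upper bounds for dRfxCas13d without guide (0.84%) and with EZH2g1 (1.35%). These bounds treat sites as independent, which several sites in 1 gene are not. They do not decide whether the transcripts are bound alike with every guide. Random gene sets matched on the number of PTBP1 clusters draw whole genes, with all their sites. Among such sets these genes lay at percentile 99.51 with EZH2g2. They held 0.37 times the mean of such sets without guide (14 sites against 37.4) and also fewer with EZH2g1 (6 against 13.0). These values argue against transcripts bound alike in these lists. The sets do not match the length or level of mature messenger RNA, so long or strongly bound transcripts are not excluded. With EZH2g2, dPspCas13b had 0 of its 625 sites in the 10 leading genes, which were picked from the dRfxCas13d list. In the 161 other genes a like effect with dPspCas13b cannot be told apart from none, with 6 sites and a ratio of 1.37 to no guide.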
